A study of Homo sapiens with 6 samples.

How the data were processed

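RNA-seq measured transcript abundance in 6 libraries of CFPAC-1 cells, a human line from a pancreatic ductal adenocarcinoma. Per the labels, total RNA was extracted with TRIzol, and 2 libraries each came from cells with a guide RNA against the bacterial gene LACZ (the control) and from cells with either of a pair of guide RNAs against SULF2, sgRNA1 and sgRNA3. Whether the guides cut DNA or repress transcription, and where in SULF2 they lie, is not given in the sources used here. The submitters' processing notes name HISAT2 2.1.0, RSEM 1.3.1, DESeq2 1.24.0 and the genome build GRCh38. The deposited table holds TPM values (transcript abundance scaled to the same total in each library) with 2 decimals for 59962 genes, of which 58884 carry Ensembl identifiers and 1078 are loci that the authors' assembly named itself. Library columns named H1 and H3 were matched to the titles S1 and S3 by the guide number that both carry. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given. The annotation release, the strandedness of the libraries and the handling of reads shared by near-identical copies are not given in the sources used here. Symbols, types and GRCh38 coordinates were taken from GENCODE 29, which held 58611 of the identifiers.

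Values were analysed as log2(TPM + 1) after removing genes with fewer than 2 libraries at a TPM of at least 1, which left 16610 genes. The labels name DESeq2, but DESeq2 was not used because TPM values are not counts, and limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) was used. The 3 groups entered a single limma fit with an intensity trend in the prior variance (3 residual degrees of freedom and 2.34 from the prior), and 3 comparisons were read from it: sgRNA1 against LACZ, sgRNA3 against LACZ, and sgRNA3 against sgRNA1. Every adjusted p of a gene is a two-sided limma p with Benjamini-Hochberg adjustment over all genes tested in that comparison, and the threshold was 0.05. A gene counted for both guides when it passed in each comparison against LACZ with the same sign. Log2 changes on this scale understate changes of genes with low TPM. The p-values measure only the spread between libraries, and the labels do not say whether the libraries of a group came from separate cultures, so that spread may be technical.

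Gene lists, comparisons, the tests of genes, lists and terms, the alternatives and the rule for naming genes were fixed before the data were examined; some tests of explanations were not. The 39 lists held 905 entries, of which 874 matched by symbol, 30 by gene identifier and 1 not at all, and the 37 lists with at least 5 tested members went into camera (limma) with a preset correlation between genes of 0.01, adjusted over lists. They cover targets of the integrated stress response, FGF and ERK signalling, TGF-beta, BMP, Wnt, Hedgehog, Notch, YAP, NF-kB, interferon, p53, hypoxia and NRF2; heparan sulfate enzymes and core proteins; unfolded-protein chaperones; MHC class I; G1/S, mitosis, glycolysis, cholesterol and fatty acid genes; epithelial, mesenchymal, matrix and protease genes; the classical and basal-like tumour subtypes and ductal identity; acinar, islet, fibroblast, endothelial, leukocyte and neural markers; and mitochondrial, immediate early and heat shock, ribosomal and histone transcripts. Camera was repeated with a correlation estimated from the libraries, and fry (limma) was run beside it. Annotation terms in the deposited table with 10 to 300 tested members were tested with a one-sided Fisher exact test among genes changed with both guides, against 14298 tested genes that carry a term.

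SULF2, its paralog SULF1 and GDF15 were always named. For both guides, the 14 raised and 14 lowered genes with the largest smaller absolute log2 change were named, given a mean TPM of at least 5 in the higher group and a symbol that is not a clone name. For each single comparison the 5 raised and 5 lowered genes with the largest absolute log2 change and no overlap between libraries were named. Up to 4 members with the smallest p were named per list. Per term, up to 4 members that passed with both guides were named, by the largest smaller absolute log2 change. Where list members called against the direction of their list are named, they were chosen after their values were seen.

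Alternatives were a pseudocount of 0.1 or 5, no filter or a TPM of at least 5, median-of-ratios scaling, quantile normalization, removal of mitochondrial genes, no variance trend, array weights, a log2 change of at least 1, fits of only the groups compared, a block for replicate number, the mean of both guides in place of the rule for both, and leaving out each library in turn. A group left with a single library was assumed to vary like the other groups. Camera with a preset correlation compares a list with other genes, so its result depends little on the number of libraries. A list that still passes with a library left out therefore adds little support. The analysis was tested on simulated data with 16610 genes: for sgRNA1, 20.9%, 67.2% and 90.9% of genes changed by a log2 of 0.5, 1 and 2 were recovered with 8 false calls, and for sgRNA3 26.9%, 61.2% and 89.4% with 14. The changed genes were drawn only from genes with a mean log2(TPM + 1) above 2, so recovery at lower TPM was not measured. A simulated set of 30 genes raised by a log2 of 0.3 gave camera an adjusted p of 1.3e-20 with the preset correlation. With an estimated one it was 0.0578. Noise was drawn separately for each gene there, so a list that fails with an estimated correlation may still have changed.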

Results

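The data were whole-transcriptome RNA-seq profiles of CFPAC-1 cells in 3 groups of 2 libraries each: LACZ control (titled LACZ_1 and LACZ_2), SULF2 sgRNA1 (S1_1 and S1_2) and SULF2 sgRNA3 (S3_1 and S3_2). SULF2 encodes an extracellular sulfatase that removes 6-O-sulfate groups from heparan sulfate, the sugar chain that holds growth factors at the cell surface. The depth of the libraries is unknown, since only TPM values are held. Between 15563 and 15923 genes per library reached a TPM of at least 1, and transcripts of the mitochondrial genome took 10.3% to 11.2% of each library. Across genes, which are not independent replicates, libraries of the same group correlated at 0.959 to 0.964 and libraries of different groups at 0.947 to 0.961. The median absolute difference between the replicates of a gene on the log2 scale was 0.14 in LACZ, 0.15 with sgRNA1 and 0.13 with sgRNA3.

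Whether the guides lowered their target was examined first. SULF2 (ENSG00000196562, chromosome 20, 47656348 to 47786616 on GRCh38) was at 25.69 and 22.52 TPM in the LACZ libraries, 8.98 and 12.81 with sgRNA1, and 10.07 and 9.24 with sgRNA3. Its mean was 24.1 ± 2.24 TPM (SD, n = 2) in LACZ, 10.9 ± 2.71 with sgRNA1 (45.2% of LACZ) and 9.65 ± 0.587 with sgRNA3 (40.1%). The log2 change was -1.09 with sgRNA1 (SE 0.18, limma adjusted p = 0.0338) and -1.23 with sgRNA3 (adjusted p = 0.0215). The test between the guides did not pass (log2 change -0.14, SE 0.18, limma adjusted p = 0.754). With sgRNA1 the call was lost without any of the libraries LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 (adjusted p = 0.172, 0.128, 0.0781, 0.0544, 0.0832 and 0.0828), without the low-value filter (0.0768), under quantile normalization (0.0530), without the variance trend (0.0675) and with only the groups compared (0.0825). With sgRNA3 it was lost without LACZ_1, LACZ_2, S3_1 or S3_2 (adjusted p = 0.117, 0.1002, 0.1004 and 0.109), without the filter (0.0528) and without the trend (0.0511). The S3_1 and S3_2 libraries do not enter the sgRNA1 comparison, and the SULF2 log2 change with sgRNA1 stayed at -1.09 without them. An exact permutation test of the 4 guide libraries against the 2 LACZ libraries gave a two-sided p of 0.0667. That is the smallest this design allows, and 2 libraries against 2 cannot go below 0.333. SULF1 (ENSG00000137573, chromosome 8), the closest paralog of SULF2, was listed at 0 in all 6 libraries.

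GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a secreted member of the TGF-beta family induced by cell stress, fell with both guides. It was at 71.7 ± 0.474 TPM (SD, n = 2) in LACZ, 20.2 ± 2.96 with sgRNA1 and 18.8 ± 1.09 with sgRNA3. Its log2 change was -1.79 with sgRNA1 (SE 0.11, limma adjusted p = 0.00259) and -1.88 with sgRNA3 (adjusted p = 0.00254). Both calls held with each library left out, and the test between the guides did not pass (log2 change -0.09, limma adjusted p = 0.741).

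**Figure D1:**
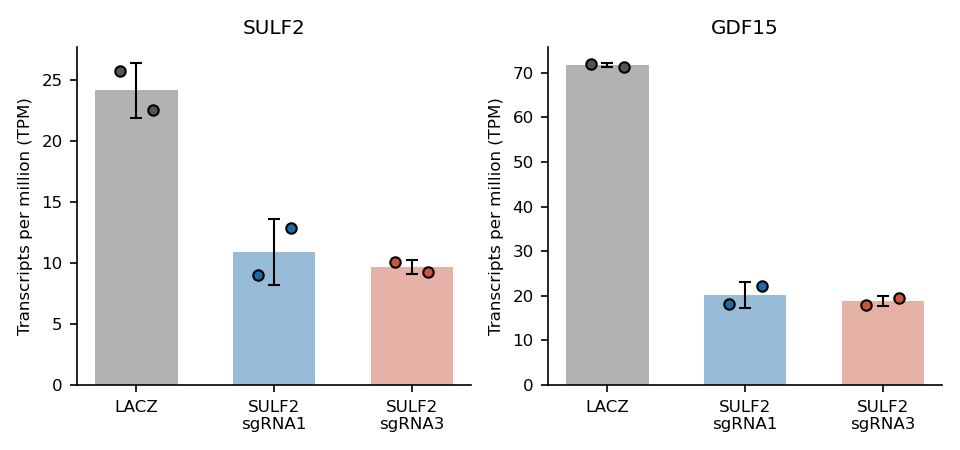
TPM of SULF2 and GDF15 in each library (points) with the group mean and SD (bars) for the LACZ, sgRNA1 and sgRNA3 groups of 2 libraries each. All 4 guide libraries lie below both LACZ libraries for each gene.

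Changes seen with both guides do not rest on a single guide, but they share the LACZ libraries. Of 32 transcripts of the integrated stress response, which cells start when amino acids run short or proteins misfold, 25 fell with both guides. So did 14 of 26 FGF and ERK targets, 14 of 32 NF-kB targets, 10 of 26 TGF-beta targets and 7 of 20 YAP targets, while 9 of 30 replication genes rose with both. Each of these lists passed camera with each guide and none passed with an estimated correlation (adjusted p = 0.0687 to 0.618). The HSP70 chaperones HSPA8, HSPA1A and HSPA1B rose. Immediate early genes, which respond to handling within minutes, also fell, in 6 of 9 with sgRNA1 and 7 of 9 with sgRNA3. They are not a separate group, since EGR1 and FOS are also ERK targets and ATF3 a stress response target. The mitochondrial ribosomal RNA MT-RNR2 was at 7800 and 7597 TPM in the LACZ libraries and 4689 to 4895 in the others. The other mitochondrial ribosomal RNA, MT-RNR1, hardly moved, at 1059 and 1060 TPM in LACZ and 976 to 1064 in the others. In all, 672 genes passed with both guides, 191 higher and 481 lower, and 3 passed in opposite directions. Of these, 180 of the 191 and 438 of the 481 are protein coding. Independent lists of these sizes would share 10.8 genes higher and 37.6 lower. Both comparisons use the same LACZ libraries, so part of the excess may come from the shared controls. In 100 simulations with no effect of either guide the overlap averaged 0.04 genes and reached at most 1, but these made only 0.21 and 0.13 calls per comparison on average and do not measure that part. The log2 changes with the guides correlated at 0.605 across genes, against 0.499 in the simulations, with a covariance of 0.156 against 0.0560. Without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 in turn, 106, 138, 180, 138, 125 and 109 genes passed with both. The split also moved with scaling: 409 higher and 390 lower under median-of-ratios scaling, and 299 and 397 under quantile normalization, where 189 and 381, and 180 and 373, of the 191 and 481 genes remained.

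**Figure D2:**
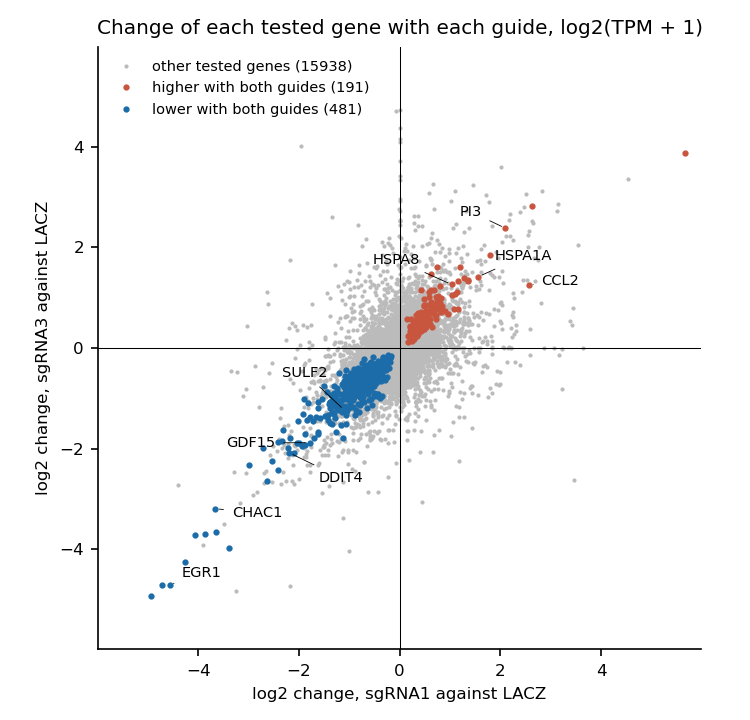
Log2 change of each of 16610 tested genes with sgRNA1 (horizontal axis) and sgRNA3 (vertical axis) against LACZ, on log2(TPM + 1). Red points are the 191 genes higher with both guides and blue points the 481 lower with both.

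Genes raised by both guides included chaperones. HSPA8, the constitutive HSP70 that folds new proteins, rose from 593 ± 35.9 TPM (SD, n = 2) in LACZ to 1213 ± 15.4 with sgRNA1 and 1421 ± 30.7 with sgRNA3 (log2 changes 1.03 and 1.26, limma adjusted p = 0.00117 and 0.00111). The heat-inducible HSPA1A rose with log2 changes of 1.56 and 1.41 and its near-identical copy HSPA1B with 1.37 and 1.33, so reads may be shared between them. ABCE1, which recycles ribosomes after translation, rose by 0.807 and 1.239. These 4 genes passed with each library left out. PI3, an elastase inhibitor secreted by epithelia, rose by 2.103 and 2.379. Its call with sgRNA1 was lost without LACZ_1, LACZ_2, S1_1 or S1_2 (adjusted p = 0.0668, 0.0568, 0.0531 and 0.0678). CCL2, a chemokine that draws monocytes, rose from 20.5 TPM to 126 and 50.03 (2.57 and 1.25), and its call with sgRNA3 was lost without S3_1 (0.0593). SKP2, which marks the cell-cycle inhibitor p27 for destruction, rose by 1.09 and 1.08; with sgRNA1 it was lost without LACZ_1, LACZ_2, S1_1 or S1_2 (0.0545, 0.0633, 0.0626 and 0.0678) and with sgRNA3 without LACZ_2, S3_1 or S3_2 (0.0633, 0.0720 and 0.0660). The other 7 of the 14 named were C4orf48, HEBP2, GTF2IRD2B (which has near-identical copies), TNFRSF10D (a decoy receptor for the death ligand TRAIL), TIMM21, ARSB (a lysosomal sulfatase) and IMP3. Each was lost without at least 1 library, each of the 6 libraries ended at least 1 of these calls (adjusted p = 0.0508 to 0.197), and ARSB was also lost under another scaling.

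Genes lowered by both guides included stress and growth-factor response factors. EGR1 (ENSG00000120738, chromosome 5), a transcription factor induced within minutes by ERK signalling, fell from 92.3 ± 0.219 TPM (SD, n = 2) to 2.96 ± 0.594 with sgRNA1 and 2.58 ± 0.17 with sgRNA3 (log2 changes -4.57 and -4.70, limma adjusted p = 3.8e-04 and 7.1e-04). CHAC1, which degrades glutathione under amino acid stress, fell from 62.3 TPM to 4.05 and 5.94. DDIT4 and SESN2, stress-induced brakes on the growth kinase mTORC1, fell with log2 changes of -2.19 and -2.08 and of -2.22 and -1.99. HBEGF, a ligand of the EGF receptor, fell from 246 TPM to 47.6 and 67.5. TXNIP, which limits glucose uptake, fell from 228 TPM to 49.7 and 65.2. JUNB and JDP2, members of the AP-1 family of transcription factors, and TNFSF18, a T-cell co-stimulatory ligand, fell by 1.89 or more with either guide. These 9 genes passed with each library left out. ATF3, a stress-induced transcription factor, fell with log2 changes of -2.64 and -2.63; without LACZ_1 the adjusted p was 0.0613 and 0.0521. INHBA, a subunit of activin, fell by 2.40 and 1.87; its calls were lost without LACZ_1 (0.0540 with sgRNA1, 0.0686 with sgRNA3) and, with sgRNA3, without LACZ_2, S3_1 or S3_2 (0.0530, 0.0616 and 0.0660). The gel-forming mucin MUC6, the zinc finger gene ZKSCAN7 and the pseudogene CHMP1B2P were also among the 14, with larger decreases than most of these genes, but their LACZ libraries were far apart (33.1 and 12.3 TPM for MUC6), and leaving out single libraries ended their calls (0.0501 to 0.169).

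Of 32 tested integrated stress response targets, 26 fell with sgRNA1 (30 adjusted over the list alone) and 25 with sgRNA3 (28 adjusted over the list alone). In all, 25 fell with both, among them GDF15, CHAC1, DDIT4, SESN2 and ATF3. These genes, described above, are therefore not separate from the list. The list's median log2 change was -1.09 with sgRNA1 (camera adjusted p = 6.8e-27, and adjusted p = 0.0891 with an estimated correlation) and -0.74 with sgRNA3 (1.3e-19, and adjusted p = 0.0687 with an estimated correlation). Members span the master factor ATF4 (log2 changes -0.96 and -0.90), its partner DDIT3 (-1.72 and -1.45), the feedback pseudokinase TRIB3 (-1.82 and -1.09) and the asparagine synthetase ASNS (-2.02 and -1.45), all of which passed with each library left out. WARS, a tRNA synthetase that interferon also induces, ran against its list with sgRNA3 (log2 change 0.36) and lost its call without any of LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 (0.0861, 0.146, 0.0806, 0.0804, 0.1004 and 0.157). With sgRNA3 the members that fell numbered 14, 16, 15 and 15 without LACZ_1, LACZ_2, S3_1 and S3_2.

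Of 26 FGF and ERK targets, 15 fell with sgRNA1 (18 adjusted over the list alone) and 17 with sgRNA3 (21 adjusted over the list alone), with 14 in common. The medians were -0.75 (camera adjusted p = 5.3e-14, and adjusted p = 0.295 with an estimated correlation) and -0.50 (1.1e-12, and adjusted p = 0.296 with an estimated correlation). AREG, an EGF receptor ligand, fell from 596 TPM to 210 and 353, the growth regulator MYC from 282 to 108 and 133, and the ERK phosphatase DUSP5 from 68.1 to 30.1 with either guide. CCND1, the ERK-induced cyclin that drives entry into the cell cycle, rose instead by 0.27 and 0.40. Its call with sgRNA1 was lost without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 or S3_2 (0.120, 0.105, 0.0796, 0.0774, 0.0687 and 0.0684), and with sgRNA3 without LACZ_1, LACZ_2, S3_1 or S3_2 (0.0628, 0.0576, 0.0656 and 0.0663). The members that fell with sgRNA3 numbered 8, 9, 9 and 9 without LACZ_1, LACZ_2, S3_1 and S3_2.

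NF-kB targets, which include chemokines and cytokines of inflammation, fell in 17 of 32 members with sgRNA1 (21 adjusted over the list alone) and 15 with sgRNA3 (19 adjusted over the list alone), 14 of them shared. The medians were -0.53 (camera adjusted p = 9.7e-08, and adjusted p = 0.295 with an estimated correlation) and -0.45 (4.2e-05, and adjusted p = 0.390 with an estimated correlation). The neutrophil chemokines CXCL8, from 827 TPM to 218 and 331, and CXCL2, from 321 to 64.0 and 103, fell together with the cytokine IL6, from 210 to 56.0 and 104. Against the list rose CCL2, the acute-phase protein SAA1 (0.43 and 0.33) and, with sgRNA3, CXCL5 (0.64), another neutrophil chemokine. The SAA1 calls were lost without any of LACZ_1, LACZ_2, S3_1 and S3_2 (0.107, 0.0963, 0.0554 and 0.0558 with sgRNA1; 0.127, 0.112, 0.126 and 0.123 with sgRNA3) and, with sgRNA1, without S1_1 (0.0526), and that of CXCL5 without S3_1 or S3_2 (0.0564 and 0.0540). The members that fell with sgRNA1 numbered 10, 9 and 9 without LACZ_1, LACZ_2 and S1_2, and with sgRNA3 7, 6, 7 and 7 without LACZ_1, LACZ_2, S3_1 and S3_2.

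TGF-beta and YAP targets overlap, since CCN2 and TGFB2 are in both lists. In all, 10 of the 26 tested TGF-beta targets and 2 of the 20 YAP targets are in another list. Of 26 TGF-beta targets, 10 fell and 0 rose with sgRNA1 (12 and 1 adjusted over the list alone) and 12 fell and 1 rose with sgRNA3 (13 and 1 adjusted over the list alone), 10 falling with both, at medians of -0.42 (camera adjusted p = 1.5e-04, and adjusted p = 0.318 with an estimated correlation) and -0.49 (3.3e-06, and adjusted p = 0.296 with an estimated correlation). JUNB is in this list too, and CCN2, a matrix protein induced by both pathways, fell from 49.1 TPM to 24.5 and 22.6, though with sgRNA1 not without LACZ_1 (0.0568). Of 20 YAP targets, 8 fell with sgRNA1 (12 adjusted over the list alone) and 7 with sgRNA3 (7 adjusted over the list alone), at medians of -0.45 (camera adjusted p = 9.1e-06, and adjusted p = 0.416 with an estimated correlation) and -0.20 (0.0151, and adjusted p = 0.618 with an estimated correlation). GADD45B, a stress-response adaptor, fell with log2 changes of -1.70 and -1.78, and ANKRD1, a direct YAP target, with -0.71 and -0.51. NT5E, the ectonucleotidase CD73, rose by 0.30 and 0.53 and lost its calls without LACZ_2, S3_1 or S3_2 (0.145, 0.0921 and 0.0917 with sgRNA1; 0.0572, 0.0616 and 0.0663 with sgRNA3) and, with sgRNA1, also without LACZ_1, S1_1 or S1_2 (0.109, 0.119 and 0.108). IGFBP3, which binds insulin-like growth factors, rose with sgRNA1 (0.28), a call lost without any of LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 (0.0707, 0.107, 0.103, 0.138, 0.0802 and 0.0806). TGF-beta targets that fell numbered 2, 4, 6 and 4 with sgRNA1 without LACZ_1, LACZ_2, S1_1 and S1_2, and with sgRNA3 7, 7, 7 and 7 without LACZ_1, LACZ_2, S3_1 and S3_2.

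Some replication genes rose, but most did not pass with either guide. Of 30 G1/S and replication genes, 10 were higher with sgRNA1 and 14 with sgRNA3, 9 of them with both. Adjusted over the list alone, 12 were higher and 1 lower with sgRNA1, and 19 higher and 1 lower with sgRNA3. The medians were 0.24 (camera adjusted p = 3.7e-10, and adjusted p = 0.0891 with an estimated correlation) and 0.34 (7.4e-13, and adjusted p = 0.0687 with an estimated correlation). PCNA, the sliding clamp of the replication polymerases, rose from 293 TPM to 455 and 481 and kept both calls with each library left out. SLBP, which binds histone mRNA in S phase, rose by 0.63 and 0.92, with the sgRNA1 call lost without LACZ_1, LACZ_2, S1_1 or S1_2 (0.0736, 0.0771, 0.0560 and 0.0735). Leaving out LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 left 1, 1, 2, 1, 4 and 3 members with sgRNA1, and with sgRNA3 2, 2, 3 and 2 without LACZ_1, LACZ_2, S3_1 and S3_2, while the list passed camera each time. Epithelial adhesion genes were lower: 9 of 28 fell with sgRNA1 (18 adjusted over the list alone) and 10 with sgRNA3 (12 adjusted over the list alone), at medians of -0.29 (camera adjusted p = 9.7e-08, and adjusted p = 0.298 with an estimated correlation) and -0.17 (0.0049, and adjusted p = 0.568 with an estimated correlation). Keratin KRT18 fell by 0.34 with sgRNA1, lost without S1_2 (0.0518), and the tight-junction claudin CLDN3 fell by 0.92 with sgRNA3, lost without LACZ_1 (0.0544). The adhesion genes that fell numbered 1, 1, 2, 0, 3 and 3 with sgRNA1 without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2, and 0, 1, 1 and 1 with sgRNA3 without LACZ_1, LACZ_2, S3_1 and S3_2; limma found 4085 genes at an unadjusted p under 0.05 with sgRNA1 and 4646 with sgRNA3 over all libraries.

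**Figure D3:**
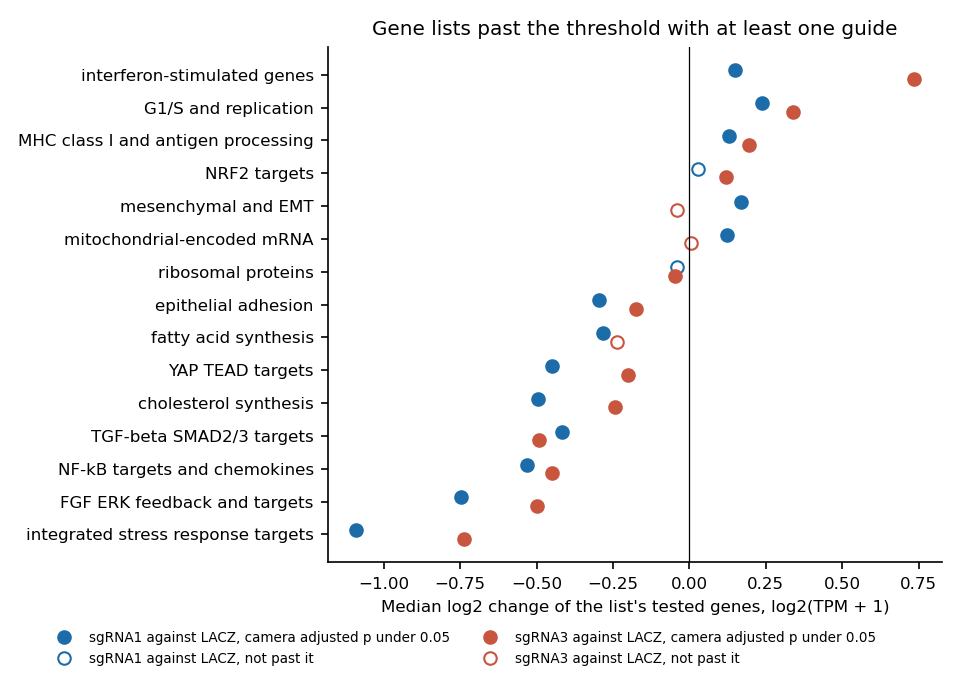
Median log2 change of each gene list that passed camera with at least 1 guide, for sgRNA1 (blue) and sgRNA3 (red) against LACZ, with filled points past the threshold and open points not. The integrated stress response list is lowest with both guides, and the interferon list is highest with sgRNA3.

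With sgRNA1 against LACZ, 997 genes passed, 281 higher and 716 lower (71.8% lower), and 13 lists passed camera, 5 higher and 8 lower, and 0 lists passed with an estimated correlation. By fry, run over all lists, 18 passed. The share of calls that were lower fell to 48.7% under median-of-ratios scaling (610 higher, 578 lower) and to 55.9% under quantile normalization (442 and 560). The genes passing numbered 150, 200, 263, 178, 346 and 310 without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2. SPP1, the secreted phosphoprotein osteopontin, rose from 5.60 ± 0.368 TPM (SD, n = 2) to 30.5 ± 4.87 (log2 change 2.25, SE 0.16, limma adjusted p = 0.00373), and it and CCL2 held with each library left out. CST1, a salivary cystatin that inhibits cysteine proteases and has near-identical copies, rose by 3.38 and was lost without S1_1 or S1_2 (0.0626 and 0.0735). VCAM1, an adhesion receptor for leukocytes, rose from 1.25 TPM to 9.97 and was lost without S1_1 or S1_2 (0.0501 and 0.0552). FAM9B, a gene mainly of testis, rose by 3.22 and was lost without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 or S3_2 (0.0933, 0.0542, 0.0739, 0.0660, 0.0554 and 0.0558). The 5 largest decreases were EGR1, MUC6, CHAC1, CHMP1B2P and ZKSCAN7, described with both guides.

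Of 25 cholesterol synthesis genes, 16 fell with sgRNA1 (19 adjusted over the list alone) and 5 with sgRNA3 (10 adjusted over the list alone). The medians were -0.50 (camera adjusted p = 6.9e-10, and adjusted p = 0.295 with an estimated correlation) and -0.24 (4.6e-04, and adjusted p = 0.435 with an estimated correlation). The sterol enzyme MSMO1 (log2 change -0.74) and the feedback regulator INSIG1 (-0.94) held with sgRNA1 for each library left out. With LACZ_1, LACZ_2, S1_1, S1_2, S3_1 or S3_2 left out, 3, 3, 6, 2, 3 and 3 members fell with sgRNA1; with sgRNA3 none did without LACZ_1, LACZ_2, S3_1 or S3_2, and the list still passed. Fatty acid synthesis genes fell in 7 of 20 members with sgRNA1 (1 higher and 10 lower adjusted over the list alone), at a median of -0.28 (camera adjusted p = 0.0017, and adjusted p = 0.333 with an estimated correlation). With sgRNA3, 5 fell (1 higher and 5 lower adjusted over the list alone; median -0.24, camera adjusted p = 0.115), though quantile normalization let that list pass (0.0413). SCD, which makes monounsaturated fatty acids, fell from 207 TPM to 127 with sgRNA1 in every fit with a library left out. Mesenchymal genes were higher with sgRNA1 at a median of 0.17 (camera adjusted p = 0.0222, and adjusted p = 0.493 with an estimated correlation), with 3 higher and 2 lower (5 and 2 adjusted over the list alone). That call was lost with a TPM of at least 5 (0.0523), under quantile normalization (0.0588) and without S1_1 (0.0963). The filament protein VIM rose by 0.24, and SNAI2, a repressor of epithelial genes, fell by 1.03 against the list; VIM was lost without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 or S3_2 (0.108, 0.0902, 0.0739, 0.0699, 0.0643 and 0.0644) and SNAI2 without LACZ_1, LACZ_2 or S1_2 (0.0878, 0.0969 and 0.0699). With sgRNA3 the list did not pass (median -0.04, adjusted p = 0.515).

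Against LACZ, sgRNA3 raised genes of the antiviral interferon response. In all, 1509 genes passed, 637 higher and 872 lower (57.8% lower), and 12 lists passed camera, 4 higher and 8 lower, and 0 lists passed with an estimated correlation. By fry, run over all lists, 19 passed. The share lower was 44.1% under median-of-ratios scaling (1020 higher, 806 lower) and 51.0% under quantile normalization (776 and 808). With LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 left out, 192, 219, 840, 852, 228 and 196 genes passed. Of 34 interferon-stimulated genes, 25 rose and 1 fell with sgRNA3 (27 and 1 adjusted over the list alone), against 4 and 1 with sgRNA1 (10 and 4 adjusted over the list alone). The median was 0.74 with sgRNA3 (camera adjusted p = 6.2e-21, and adjusted p = 0.0687 with an estimated correlation) and 0.15 with sgRNA1 (4.3e-04, and adjusted p = 0.295 with an estimated correlation). Across the list, the median level in log2(TPM + 1) was 5.57 and 5.64 in S3_1 and S3_2. It was 4.94 and 4.86 in S1_1 and S1_2 against 4.94 and 4.98 in LACZ_1 and LACZ_2, so by this measure sgRNA1 showed no rise. ISG15, a ubiquitin-like modifier, rose from 620 TPM in LACZ to 1149.6 with sgRNA3, the antiviral GTPase MX1 from 137 to 303, IFIT1, which binds viral RNA, from 39.5 to 111, and IFI6 from 238 to 532. All 4 held with each library left out. IRF1, an interferon-induced transcription factor that NF-kB also drives, fell instead by 0.67, and lost that call without LACZ_1, LACZ_2, S3_1 or S3_2 (0.112, 0.110, 0.0808 and 0.0539). Without LACZ_1, LACZ_2, S3_1 and S3_2 the members that rose numbered 11, 11, 10 and 9. With sgRNA1, IFIT1 rose by 0.63 and IRF1 fell by 0.81, each lost without LACZ_1, LACZ_2, S1_1 or S1_2 (0.0821, 0.0818, 0.0626 and 0.0724; 0.110, 0.101, 0.0608 and 0.0918). Without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 the members that rose with sgRNA1 numbered 0, 0, 0, 0, 2 and 1, and 9 under median-of-ratios scaling.

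**Figure D4:**
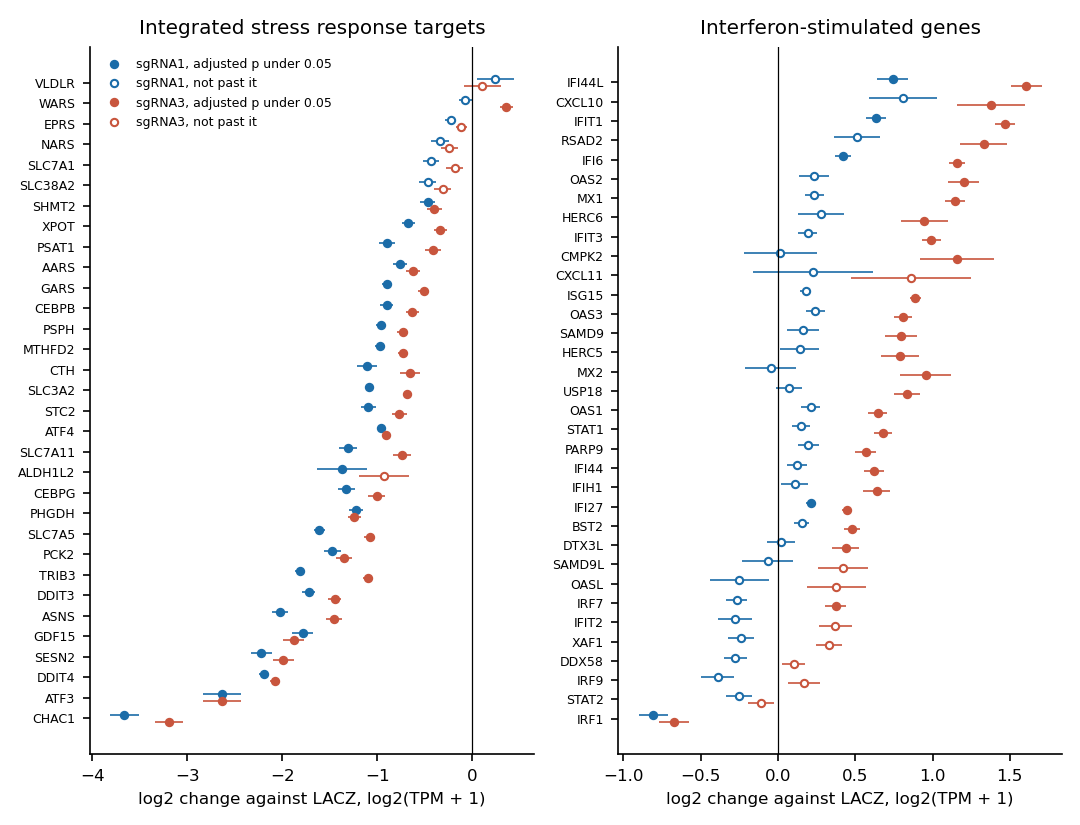
Log2 change and SE of each tested integrated stress response target and interferon-stimulated gene with sgRNA1 (blue) and sgRNA3 (red) against LACZ, with filled points past an adjusted p of 0.05. Most stress response targets lie below 0 with both guides, and 25 interferon-stimulated genes lie above 0 past the threshold with sgRNA3.

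The largest increase with sgRNA3 was the readthrough transcript CCDC169-SOHLH2, at 0.045 TPM in LACZ and listed at 0 with sgRNA1. With sgRNA3 it was at 27.6 ± 11.6 TPM (SD, n = 2), a log2 change of 4.71 (limma adjusted p = 0.00333, held with each library left out). LACZ is near 0, so the size depends on the pseudocount, and it ranged from 2.64 to 7.51 across the alternatives. FAM220A, a STAT3-binding protein, rose by 2.44 and was lost without LACZ_1, LACZ_2, S3_1 or S3_2 (0.0619, 0.0633, 0.0616 and 0.0513). S100P, a calcium-binding protein common in pancreatic tumours, rose by 1.99 and was lost without LACZ_1 or S3_1 (0.0534 and 0.0616). TXNDC5, a protein disulfide isomerase, rose by 1.87, and the non-coding LINC01572 and the histone gene HIST1H4J fell by 4.82 and 3.37, with wide spreads. These 3 calls were lost without LACZ_1, LACZ_2, S3_1 or S3_2 (TXNDC5 0.106, 0.0518, 0.171 and 0.144; LINC01572 0.148, 0.184, 0.159 and 0.167; HIST1H4J 0.169, 0.164, 0.133 and 0.0717), and TXNDC5 and HIST1H4J also without S1_1 or S1_2 (0.0771 and 0.0765; 0.0616 and 0.0610). NRF2 targets, which counter oxidants and store iron, rose in 4 of 24 members and fell in 1 (4 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.0242, and adjusted p = 0.313 with an estimated correlation). The call was lost under quantile normalization (0.0758), without the variance trend (0.0725) and without LACZ_1 (0.0703). The ferritin chains FTL and FTH1 rose by 0.58 and 0.54 in every fit with a library left out, while SLC7A11, a cystine importer that ATF4 also drives, fell by 0.74 and was lost without LACZ_1, LACZ_2, S3_1 or S3_2 (0.0948, 0.0979, 0.0933 and 0.0822). With sgRNA1 the NRF2 list did not pass (2 higher and 1 lower, 3 and 1 adjusted over the list alone, median 0.03, mean -0.02, adjusted p = 0.252). Of 16 MHC class I and antigen processing genes, 6 rose and 1 fell with sgRNA3 (7 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.0015, and adjusted p = 0.296 with an estimated correlation), and 2 rose and 1 fell with sgRNA1 (5 and 3 adjusted over the list alone; median 0.13, mean -0.00, adjusted p = 0.0385, and adjusted p = 0.378 with an estimated correlation). The sgRNA1 call was lost with a TPM of at least 5 (0.0523), under quantile normalization (0.189), without the trend (0.107), with only the groups compared (0.0771) and without S1_1, S3_1 or S3_2 (0.107, 0.0737 and 0.0742). CD274, the checkpoint ligand PD-L1, fell against the list by 1.39 and 1.08; the calls were lost without LACZ_1 or LACZ_2 (0.0675 and 0.0532 with sgRNA1, 0.0788 and 0.0744 with sgRNA3), with sgRNA1 without S1_2 (0.0518) and with sgRNA3 without S3_2 (0.0581).

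The test of sgRNA3 against sgRNA1 asks where the guides themselves differ. By camera 19 lists passed, 13 higher and 6 lower with sgRNA3, and 0 with an estimated correlation. In all, 96 genes passed, 65 higher and 31 lower with sgRNA3 (32.3% lower, against 44.7% under median-of-ratios scaling and 44.4% under quantile normalization). Without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 in turn, 2, 2, 8, 0, 27 and 0 passed, and limma found 2550 genes at an unadjusted p under 0.05 over all libraries. Of genes called with sgRNA1 alone, 89 were higher and 233 lower, of which 12 and 10 differed by the test between the guides. Of those called with sgRNA3 alone, 444 were higher and 390 lower, of which 29 and 13 differed. Interferon-stimulated genes were higher with sgRNA3 at a median difference of 0.63, with 11 of 34 passing (31 adjusted over the list alone; camera adjusted p = 2.1e-27, and adjusted p = 0.0957 with an estimated correlation). MX1 differed by 0.91 and ISG15 by 0.71; MX1 was lost without any of LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 (0.0733, 0.0731, 0.0842, 0.113, 0.0657 and 0.0896) and ISG15 without LACZ_1, LACZ_2, S1_1, S1_2 or S3_2 (0.0717, 0.0714, 0.0563, 0.0972 and 0.0712). The interferon genes that passed numbered 0, 0, 0, 0, 1 and 0 without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2, and 7 and 8 under median-of-ratios scaling and quantile normalization.

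Calls of other single genes between the guides were also lost when libraries were left out. The LACZ libraries do not enter this difference, so leaving them out alters only the estimate of the spread. CCDC169-SOHLH2 was higher with sgRNA3 by 4.77 (2.66 to 8.05 across the alternatives). Also higher were FAM220A by 3.26, RGS4, a brake on G protein signalling, by 1.20, and the antiviral sensor OAS2 by 0.97. Lower with sgRNA3 were FAM9B (log2 difference -4.03), the near-identical cystatins CST1 and CST4 (-2.85 and -2.72), VCAM1 (-2.56) and QPRT, an enzyme of NAD synthesis (-2.17). Without LACZ_1, LACZ_2, S1_1, S1_2, S3_1 or S3_2 the adjusted p of these 9 genes lay between 0.0522 and 0.210, except that CCDC169-SOHLH2 held without S3_1. In addition, all 9 were lost without the filter and with only the groups compared, and all but FAM220A and VCAM1 without the variance trend. OAS2 was also lost under median-of-ratios scaling (0.0541) and quantile normalization (0.0526), and CST4 with a pseudocount of 0.1 (0.0564), a TPM of at least 5 (0.0588) and array weights (0.0513). The list of stress response targets passed as higher with sgRNA3 than with sgRNA1 at a median of 0.26 (3 of 32 passing, 17 adjusted over the list alone; camera adjusted p = 1.3e-10, and adjusted p = 0.250 with an estimated correlation), as did cholesterol genes (median 0.23, 2 passing, 11 adjusted over the list alone; 6.4e-07, and adjusted p = 0.262 with an estimated correlation), ERK targets (0.12, 4 passing, 8 adjusted over the list alone; 0.0013, and adjusted p = 0.349 with an estimated correlation) and NF-kB targets (0.31, 7 higher and 2 lower, 13 and 2 adjusted over the list alone; 1.7e-04, and adjusted p = 0.301 with an estimated correlation). Without any of LACZ_1, LACZ_2, S1_1, S1_2, S3_1 or S3_2, 0 members of these 4 lists passed limma, except 1 ERK target without S3_1, while the lists themselves still passed.

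Annotation terms were tested on the same genes changed with both guides, and most members named below are also in the fixed lists. The terms are therefore not separate support. Fisher's exact test also treats genes that move together as independent. Of 3786 terms tested, 84 were enriched among genes raised with both guides and 139 among genes lowered (Fisher's exact test, Benjamini-Hochberg adjusted). Without LACZ_1, LACZ_2, S3_1 and S3_2, 101, 94, 105 and 109 terms passed. Among raised genes were the DNA replication pathway (8 of 38 members, among them PCNA; adjusted p = 2.3e-05), protein refolding (6 of 29, among them HSPA1A, HSPA1B and HSPA8; 4.7e-04), the proteasome complex (7 of 66; 0.00266) and iron ion transport (4 of 15, among them FTH1 and FTL; 0.00353). Among lowered genes were TNF signalling (19 of 106, among them JUNB, CXCL2 and the prostaglandin synthase PTGS2; 2.6e-06), the cellular response to hypoxia (17 of 87, among them MYC and the vessel growth factor VEGFA; 3.4e-06), amino acid biosynthesis (9 of 32, among them ASNS and the serine synthesis enzyme PHGDH; 1.9e-04), growth factor activity (14 of 87, among them HBEGF and GDF15; 2.2e-04) and the PERK branch of the unfolded protein response (6 of 13, among them ATF3, ASNS, DDIT3 and CXCL8; 4.2e-04). The fixed hypoxia list, by contrast, did not pass camera with either guide.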

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

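No test in this part was chosen after its result was seen. A trio of genes passed with both guides in opposite directions and also differed by the test between the guides. CP encodes ceruloplasmin, a copper protein that oxidises iron, and was at 7.49 TPM in LACZ, 15.5 with sgRNA1 and 3.37 with sgRNA3 (log2 changes 0.97 and -0.95, log2 difference -1.92, limma adjusted p of the difference 0.0254). G0S2, an inhibitor of the lipase that breaks down stored fat, was at 46.9, 35.5 and 59.2 TPM (-0.39 and 0.33, log2 difference 0.72, adjusted p = 0.0174). PTHLH, the parathyroid hormone-like hormone that many carcinomas secrete, was at 129, 106 and 179 TPM (-0.28 and 0.47, log2 difference 0.75, adjusted p = 0.0174). Both libraries of each group lay apart from those of the other groups for all 3 genes, but none of the 3 differences held with a library left out. With LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 left out in turn, the adjusted p of the difference was 0.0795, 0.0770, 0.111, 0.163, 0.0890 and 0.120 for CP, 0.0795, 0.0770, 0.0837, 0.107, 0.0922 and 0.101 for G0S2, and 0.0795, 0.0770, 0.0578, 0.0972, 0.0697 and 0.0793 for PTHLH. The differences were also lost without the filter (0.0748 for CP, 0.0642 for G0S2 and PTHLH), without the variance trend (0.103, 0.123 and 0.123) and with only the groups compared (0.0816 each). The calls against LACZ were lost without each of the 6 libraries for CP (0.0783 to 0.165 with sgRNA1, 0.0682 to 0.137 with sgRNA3), G0S2 (0.0670 to 0.120 and 0.0504 to 0.130) and PTHLH with sgRNA1 (0.0750 to 0.143), and for PTHLH with sgRNA3 without LACZ_1, LACZ_2, S3_1 or S3_2 (0.0655, 0.0574, 0.0682 and 0.0660). The PTHLH decrease with sgRNA1 was also lost under median-of-ratios scaling (0.0514). No gene list passed with both guides in opposite directions, and no explanation was tested for these 3 genes.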

How the results depend on the processing

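No test in this part was chosen after its result was seen. Under a pseudocount of 0.1 or 5, a TPM of at least 5, median-of-ratios scaling, removal of mitochondrial genes and array weights, SULF2 kept its calls and the total of genes, lists and terms stayed within 1.5 times. Their directions did not all do so: under median-of-ratios scaling higher calls went from 281 to 610 with sgRNA1, 637 to 1020 with sgRNA3 and 191 to 409 with both, terms of raised genes from 84 to 130 and higher lists with sgRNA1 from 5 to 9, and to 3 with a TPM of at least 5. Under quantile normalization higher calls were 442 with sgRNA1 and 299 with both, and higher lists with sgRNA1 numbered 3. Terms of raised genes were 30 without the filter and 54 with only the groups compared, and lower lists with sgRNA1 went from 8 to 14 with fry. Of 7417 alternative values of the 437 named gene results, 5086 kept their direction and side of the threshold, 2329 kept the direction but no longer passed, 0 newly passed and 2 reversed. All these results were chosen as passing, except SULF2 and GDF15 between the guides, so no others could newly pass. The counts that moved follow in the order sgRNA1, sgRNA3, sgRNA3 against sgRNA1, both guides, and terms where these moved. They were 173, 237, 25, 96 and 71 with a log2 change of at least 1, by construction; 542, 785, 0 and 378 without the filter, where low-value genes enter the adjustment; and 295, 557, 12, 194 and 117 without the variance trend, for which the cause was not tested. With only the groups compared, where a fit holds fewer samples, they were 311, 833, 2 and 219. Beside the 0 between guides without the filter, limma over filtered genes had 2550 at an unadjusted p under 0.05. Taking the mean of the guides in a single contrast gave 1803 genes in place of 672, since it asks for less than passing with each guide. Lists that passed numbered 0 and 0 with an estimated correlation, which allows for genes that move together. They numbered 18 and 19 with fry, which does not compare a list with other genes. A simulated raised set with noise drawn separately for each gene also failed with an estimated correlation (camera adjusted p = 0.0578). Failing there therefore does not decide whether a list changed. SULF2 with sgRNA1 no longer passed without the filter (log2 change -1.09), under quantile normalization (-0.99), without the trend (-1.09) and with only the groups compared (-1.09), and with sgRNA3 without the filter and without the trend (-1.23 each); the cause was not tested.

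With each library left out in turn, a fit has fewer samples. Leaving out a library of a group outside a comparison keeps that comparison's log2 changes and alters only the estimate of the spread. The results ranged as follows. SULF2 changed by -1.33 to -0.86 with sgRNA1 and by -1.33 to -1.14 with sgRNA3. Genes passing numbered 150 to 346 with sgRNA1, 192 to 852 with sgRNA3, 0 to 27 between the guides, 106 to 180 with both, and terms 94 to 182. The 2 reversed values were uncalled throughout: between the guides, SULF2 ranged from -0.375 to 0.0933 and GDF15 from -0.236 to 0.0502, each positive without S1_2 (adjusted p = 0.837 and 0.859). The replicate numbers did not pair the libraries, since the deviations of equal numbers correlated at -0.0179, 0.00611 and -0.0314 across genes. A block for replicate number gave 377, 561, 0, 245 and 129 and ended the SULF2 calls (log2 changes -1.09 and -1.23, adjusted p = 0.0819 and 0.0583). Depth is unknown and limits the low-TPM genes in a way these values cannot show.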

Other observations

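The tests of gene length and GC content on all list members, of the culture state of the LACZ cells and of the remaining SULF2 level were chosen after the result was seen, and the criterion of the last was revised after its value was seen: its bound first had to lie below the share of the SULF2 change, which it did, and now below 0, which it does not. Several gene groups did not pass as lists but held single genes that passed. Hypoxia genes fell in part: VEGFA, which drives vessel growth, fell from 639 TPM to 306 with sgRNA1 and 315 with sgRNA3 with each library left out, while the list did not pass (22 members; 1 higher and 4 lower with sgRNA1, 1 and 7 with sgRNA3, 4 and 5 and 5 and 11 adjusted over the list alone; medians -0.16 and -0.40, camera adjusted p = 0.890 and 0.262). Glycolysis genes gave 0 higher and 3 lower and 0 and 6 of 20 (2 and 4 and 4 and 7 adjusted over the list alone; medians -0.01 and -0.09, 0.890 and 0.495), with PGK1 lower by 0.47 with sgRNA3. Of 22 p53 targets 1 rose and 4 fell with sgRNA1 and 1 rose and 2 fell with sgRNA3 (1 and 8 and 1 and 3 adjusted over the list alone; medians -0.15 and -0.16, 0.262 and 0.205), among them GADD45A, a stress gene that ATF4 also drives, by 1.20 and 1.05. Unfolded-protein chaperones did not follow the stress response genes (23 members; 0 and 1, 2 and 2; 2 and 2, 4 and 3 adjusted over the list alone; medians 0.02 and -0.01, means -0.00 and 0.01, both tests upward; 0.325 and 0.857), although XBP1, the factor that induces them, fell by 0.78 and 0.72. Mitosis genes gave 1 and 0 and 0 and 1 of 30 (0 and 0 and 0 and 1 adjusted over the list alone; medians 0.03 and -0.04, 0.123 and 0.420), but with sgRNA1 the list passed upward under median-of-ratios scaling (0.00289), as did the chaperones (0.0314).

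Few genes of the sulfation machinery around SULF2 passed. Of 22 heparan sulfate enzymes, 0 rose and 2 fell with sgRNA1 and 1 rose and 1 fell with sgRNA3, SULF2 itself included (0 and 2 and 5 and 2 adjusted over the list alone; medians 0.06 and 0.12, mean -0.01 with sgRNA1, camera adjusted p = 0.146 and 0.117). The sgRNA1 list passed upward under median-of-ratios scaling (0.0492) and quantile normalization (0.0306), and the sgRNA3 list without the filter (0.0496). Of 15 core proteins 0 and 1, and 1 and 3, changed (0 and 1 and 1 and 5 adjusted over the list alone; medians -0.04 and -0.21, mean 0.03 with sgRNA1; 0.890 and 0.420), and between the guides they passed as lower with sgRNA3 without the filter (0.0430), under median-of-ratios scaling (0.0356) or quantile normalization (0.0385), without the trend (0.0434) and without S1_2 (0.0172). Signalling lists that did not pass were BMP (7 members; 1 and 0, 0 and 3; medians -0.14 and -0.12, the first against a mean of 0.10 and an upward test; 0.890 and 0.232), Wnt (14; 1 and 2, 2 and 2; -0.14 and -0.02, the latter against an upward test; 0.678 and 0.998), Notch (8; 2 and 3, 1 and 2; -0.14 and -0.04; 0.697 and 0.954) and Hedgehog (6; none; -0.09 and -0.14, the first against an upward test; 0.890 and 0.856). DKK1, a secreted Wnt inhibitor, fell by 0.55 with sgRNA1 with each library left out. Adjusted over the list alone, the counts were 1 and 0 and 0 and 3 for BMP, 2 and 4 and 2 and 3 for Wnt, 2 and 3 and 3 and 2 for Notch, and none for Hedgehog. Tumour identity did not shift as lists: the classical subtype (15; 2 and 1, 3 and 1; 0.02 and 0.01; 0.325 and 0.420), the basal-like subtype (20; 1 and 2, 3 and 1; -0.23 and -0.02, the latter against an upward test; 0.109 and 0.799) and ductal identity (19; 2 and 3, 1 and 5; -0.07 and -0.09, the first against a mean of 0.13; 0.814 and 0.524). The basal-like list passed downward with sgRNA1 without the filter (0.0421) and without S1_1 (0.0443). Adjusted over the list alone these gave 3 and 3 and 4 and 1, 2 and 9 and 4 and 5, and 4 and 5 and 2 and 5. Of 29 matrix genes 1 and 3, and 3 and 2, changed (1 and 3 and 4 and 5 adjusted over the list alone; -0.15 and -0.06, the latter against an upward test; 0.361 and 0.958), and of 26 proteases and inhibitors 3 and 4, and 3 and 7 (5 and 7 and 5 and 8 adjusted over the list alone; -0.01, against an upward test, and -0.07; 0.916 and 0.420). SERPINE2, an inhibitor of thrombin and plasminogen activators, rose by 1.08 and 0.77 with each library left out.

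Markers of other cells and of RNA quality were measured the same way. Islet markers gave 0 calls of 5 (medians 0.14 and 0.02, the latter against a mean of -0.05; 0.467 and 0.954), neural 0 of 6 (-0.18 and -0.10; 0.814 and 0.524), acinar 0 of 4 (0.34 and 0.24) and endothelial 0 of 3 (-0.09 and -0.01), the last pair too few for a list test, where adjusted over the list alone 1 neural gene passed, as lower with sgRNA3. Over all genes limma had 4085 and 4646 genes at an unadjusted p under 0.05. Fibroblast markers gave COL1A1 lower with each guide (5 tested; the same adjusted over the list alone; -0.06 and -0.25; 0.814 and 0.420) and leukocyte markers LAPTM5 higher with sgRNA1 and CD68 with sgRNA3 (5 tested; 1 and 0 and 2 and 1 adjusted over the list alone; 0.08 and -0.24, the latter against an upward test; 0.252 and 0.954). The COL1A1 call with sgRNA1, and those of LAPTM5 and CD68, were lost without any of LACZ_1, LACZ_2, S1_1, S1_2, S3_1 and S3_2 (0.179, 0.157, 0.113, 0.157, 0.0636 and 0.0627; 0.0926, 0.124, 0.0983, 0.142, 0.0803 and 0.0808; 0.146, 0.160, 0.0503, 0.0501, 0.143 and 0.168). Mitochondrial mRNAs were higher with sgRNA1 (4 of 13, 7 adjusted over the list alone; median 0.12, camera adjusted p = 4.0e-07, and adjusted p = 0.295 with an estimated correlation), not under quantile normalization (0.139), and did not pass with sgRNA3 (2 higher and 1 lower, 4 and 3 adjusted over the list alone; 0.00; 0.420). Ribosomal protein genes were lower with sgRNA3 (1 higher and 5 lower of 33, 1 and 11 adjusted over the list alone; -0.05; 0.0242, and adjusted p = 0.618 with an estimated correlation), which was lost under median-of-ratios scaling (0.648), without the trend (0.351) and without LACZ_2 or S3_2 (0.114 and 0.0904); with sgRNA1 (1 and 0, 1 and 0 adjusted over the list alone; -0.04; 0.890) they passed upward under median-of-ratios scaling (0.00918) and downward under quantile normalization (0.00271). Immediate early and heat shock genes went both ways (18; 4 and 7, 5 and 9; 7 and 11, 7 and 11 adjusted over the list alone; -0.37 and -0.45; camera 0.467 and 0.385, fry 0.0013 and 0.0010). Histone genes gave 2 and 0 with each guide of 19 (2 and 2 and 5 and 0 adjusted over the list alone; -0.29 and 0.14; 0.814 and 0.0559), and with sgRNA3 passed without the filter (0.0496), with a TPM of at least 5 (0.00373), without mitochondrial genes (0.0484) and without LACZ_2 (0.0270).

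Further lists differed between the guides, with the camera adjusted p and then the adjusted p with an estimated correlation in brackets. Beyond the interferon, stress response, ERK, NF-kB and cholesterol lists, those higher were basal-like (median 0.20; camera adjusted p = 1.1e-04, and adjusted p = 0.301 with an estimated correlation), G1/S (0.11; 0.0012 and 0.262), histones (0.42; 0.0013 and 0.262), fatty acid (0.17; 0.0071 and 0.301), NRF2 (0.10; 0.0103 and 0.262), MHC class I (0.08; 0.0118 and 0.3001), YAP (0.20; 0.0129 and 0.504) and epithelial (0.10; 0.0184 and 0.452). Lower were mitochondrial mRNA (-0.12; 3.1e-06 and 0.262), mesenchymal (-0.21; 9.7e-05 and 0.3001), mitosis (-0.09; 4.3e-04 and 0.3001), ribosomal (-0.04; 5.7e-04 and 0.323), BMP (-0.29; 0.0023 and 0.3001) and hypoxia (-0.18; 0.0118 and 0.262). Adjusted over the list alone, members higher and lower numbered 10 and 1, 3 and 1, 3 and 0, 7 and 1, 6 and 1, 3 and 0, 6 and 0, and 4 and 1 in the former lists, and 0 and 6, 1 and 4, 0 and 0, 0 and 3, 0 and 3, and 1 and 2 in the latter. Lost without S1_1 were hypoxia, epithelial and NRF2 (0.0502 each) and histones (0.0599); without S1_2 MHC class I, YAP and ribosomal (0.0798 each) and BMP (0.0624); without S3_2 epithelial (0.0929). Median-of-ratios scaling ended epithelial (0.0567) and MHC class I (0.0677), and quantile normalization mitochondrial mRNA (0.389). A TPM of at least 5 ended hypoxia (0.0647) and no trend epithelial (0.108). Some lists were gained. Leukocyte markers passed as lower with sgRNA3 without the filter (camera adjusted p = 0.0430) or trend (0.0434) and with only the groups compared (0.0339). So did Hedgehog targets without the filter (0.0400), and proteases (0.0335) and glycolysis (0.0486) under median-of-ratios scaling.

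Stress response and ERK target transcripts were lower with both guides: the 58 tested members had medians of -0.93 and -0.69, and of 40 called with both, 39 were lower. Gene length and GC content were argued against as the cause, since the medians of all 58 members were -0.87 and -0.636 after the length trend was removed and -0.86 and -0.618 after the GC trend. A different culture or harvest state of the LACZ cells cannot be told apart from SULF2 knockdown, since the labels give no plate or date. The 9 immediate early genes, which serum or handling induces, had medians of -0.946 and -1.03, with 6 and 7 lower. Of these genes, EGR1, FOS and ATF3 are also among the 58 members, so their fall in part restates the pattern. The 9 heat shock genes went the other way (medians 0.36 and 0.39, 4 and 5 higher, 1 and 2 lower), so a common loss of every stress gene does not describe the libraries. Altered ligand signalling at the surface, with SULF2 RNA at 45.2% of LACZ with sgRNA1 and 40.1% with sgRNA3, may be a further explanation. It stays untested, since neither signalling nor heparan sulfate was measured.

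Interferon-stimulated transcripts were higher with sgRNA3 than with sgRNA1 by a median log2 of 0.63. Scaling of the libraries left 0.575 under quantile normalization and 0.60 under median-of-ratios scaling. Leukocyte RNA in the sgRNA3 libraries would raise leukocyte markers, but the median of 18 markers differed by -0.12 TPM (0.163 with sgRNA1, 0.0425 with sgRNA3), CORO1A was at 11.8 and 8.67 TPM, PTPRC at 0.04 and 0.025, and TYROBP was listed at 0; none of the 5 tested passed as higher. The remaining SULF2 level stays open. With sgRNA1 the SULF2 change was 0.886 of that seen with sgRNA3. The interferon change was 0.204 of it (95% bootstrap bounds 0.0534 and 0.289, 10000 draws over genes and not libraries). This bounds only a response in proportion to SULF2. The SULF2 share has no bounds here. Without S1_1 and S1_2 in turn, the SULF2 change with sgRNA1 was -0.859 and -1.33, against -1.23 with sgRNA3. The median level of the interferon list did not rise with sgRNA1 (4.94 and 4.86 against 4.94 and 4.98 in LACZ). A response to the sgRNA3 guide or its cells other than through the SULF2 level may be another explanation and was not tested.

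More genes were lower than higher with sgRNA1, 71.8% of 997. Scaling of the libraries stays open: the share was 48.7% under median-of-ratios scaling, but that scaling centres the median change (-0.0697 before, 0.00276 after) and so fixes the balance. Among calls with a log2 change of at least 1, 128 of 173 (74.0%) were lower. Non-coding RNA carried into the LACZ libraries is argued against: genes that are not protein coding made up 7.82% of lower and 7.83% of higher calls (difference -0.00795 percentage points, Fisher's exact p = 1). Such genes made up 22.1% of those tested. Unspliced RNA of protein coding genes would leave these shares as they are, so the test cannot decide on it. Of the libraries S1_2 stood apart, with 7.06% of its TPM in nuclear genes that are not protein coding against 4.797% to 5.23% in the others; without it the median change was -0.0417 and 69.7% of 178 calls were lower.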
